A study of Panicum virgatum with 54 samples.

How the data were processed

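Leaf RNA of switchgrass (Panicum virgatum), genotype AP13, was profiled by RNA sequencing in 54 libraries. They form 18 groups of 3, made of 3 treatments (control, drought, and drought followed by heat, here called combined stress) and 6 times (0, 72, 96, 120, 144 and 168 h). Groups and times were taken from the sample titles. The titles of 3 combined libraries read 94 h with 24 h of heat. They were taken as 96 h, the time that the series design and the table's column names give. The 1 week titles were taken as 168 h, and they give no hours of heat. Per the labels' protocols, control and drought plants shared a growth chamber and combined plants stood in a separate one, so chamber and heat go together in comparisons of heated plants, while at 0 and 72 h the titles give combined plants no heat. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may in part be technical. They also do not say whether libraries of the same number at different times came from the same plant, and the edgeR model treats all libraries as independent.

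Per the labels, libraries were made with a stranded mRNA kit. Per the submitters' processing notes, TopHat, Cufflinks and HTSeq were used, without versions or roles. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds whole-number read counts per gene, not normalized, for 32190 gene identifiers of the Pavir v4.1 form. All 54 columns were used. Where the counting split reads between near-identical copies, such as gene pairs on the K and N subgenomes of this polyploid grass, the value of each copy is uncertain, and the same holds for overlapping genes. The deposited table does not pair identifiers with gene names. Of the 32190 identifiers, 0 matched an identifier among the 74976 genes in the RefSeq table for the P.virgatum_v5 assembly. The 30 gene lists prepared for heat, drought, photosynthesis and other processes were therefore not evaluated, and genes are given by identifier only. The chromosome of a gene is the one coded in its identifier (1K to 9K and 1N to 9N, or J for sequence placed on no chromosome).

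Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with the default expression filter (a minimum count of 10 and a minimum total of 15), which left 32011 genes and removed 179, and libraries were scaled by the trimmed mean of M values. A quasi-likelihood model with a mean for each of the 18 groups was fitted to all 54 libraries, which share an estimate of the spread. Contrasts of group means gave log2 fold changes with standard errors (SE). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons, the rule for naming genes and the alternative settings were fixed before the data were examined. With no gene names, that rule takes, for each of the 4 main comparisons, the 2 rising and the 2 falling called genes with the smallest p and a mean of at least 5 CPM (the usual unit of counts scaled by library size). Levels of single genes are scaled CPM, as mean ± SD over libraries. Principal components used log2 CPM with a prior count of 2.

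Total counts ran from 19.2 to 61.6 M (M for mega) per library, with a median of 34.6 M. The common biological coefficient of variation was 0.433, a spread between libraries that comes on top of counting error. In replicate pairs, counts differed by at least 23.4 times the sampling variance per gene, so no replicate appeared to be a copy of another of its group. The tests were tried on simulated counts with 200 changed genes, all with a mean of at least 5 CPM. The simulated libraries were independent, with a spread set by the mean level of a gene and no other difference between groups. Libraries of the same number were not correlated, so recovery in the real data may be lower. For the mean drought comparison, over 31973 genes, 89% of genes changed 2-fold and 100% of those changed 4-fold were recovered. For the mean of combined stress against drought, over 31981 genes, the shares were 72% and 100%. For drought at 96 h alone, over 31973 genes, they were 6% and 73%.

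The alternative settings were DESeq2 1.42.0, its size factors in the edgeR model, looser and stricter expression filters, the replicate number as a block, models of only the groups compared, a fold threshold, other sets of times and leaving out each library in turn. A search without group labels was run among the 9 libraries at 0 h, over 31787 genes with a mean count of at least 20, for genes whose log2 CPM (with 0.5 added) falls into separate levels at least 2 log2 units apart. Alternatives built on its result were chosen after the data were seen, as were limma 3.58.1 (voom) and limma with a correlation among libraries of the same number in a treatment, estimated at 0.204 over 9 sets of libraries. Subgenomes and chromosomes were compared with Fisher's exact test, two-sided, and chromosomes also with all 32011 rotations of the calls along the order of identifiers, both chosen after the data were seen.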

Results

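Switchgrass is a perennial C4 grass. AP13 is a genotype of the lowland cultivar Alamo. The study followed leaf transcripts of AP13 under drought, and under drought with heat added after 72 h, next to untreated controls. Each of the 18 treatment-by-time groups held 3 libraries, 18 libraries per treatment. Total counts ran from 19.2 to 61.6 M per library (M for mega). Within groups, log2 CPM correlated across genes at 0.755 to 0.975 (median 0.898), against a median of 0.852 between groups. The first 2 principal components held 26.7% and 17.7% of the variance. The 10 most abundant genes of a library took 2.87% to 7.60% of its counts.

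**Figure D1:**
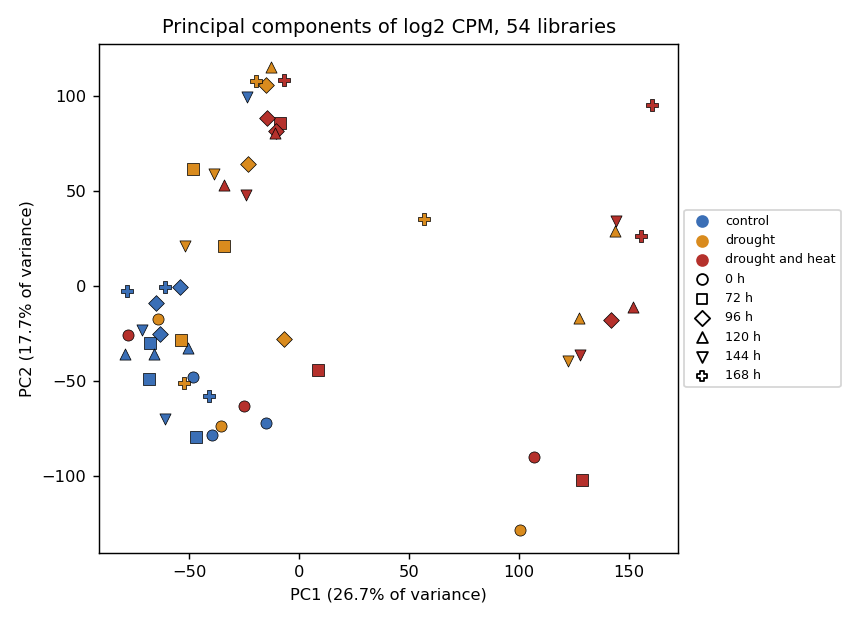
Each point is a library placed by the first 2 principal components of log2 CPM (26.7% and 17.7% of the variance), with color for treatment and symbol for time in hours. Libraries of the same group can lie far apart, and the lowest correlation within a group was 0.755. The 12 libraries at 100.4 or above on the first component are those of the second profile described below.

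A set of 405 genes was nearly absent from 12 of the 54 libraries. The set came from a search among the 9 untreated 0 h libraries without their labels, in which 411 genes separated drought replicate 1 and combined replicate 2 from the other 7, 405 lower and 6 higher in those libraries. The median level of the 405 genes there was 0.631% of that in the others. Scaled so that the 7 libraries average 1, all 12 libraries lay between -0.0022 and 0.0055. They were 0 control libraries, 4 drought libraries (0 h replicate 1, 120 h replicates 1 and 2, 144 h replicate 1) and 8 combined libraries (0 h, 72 h, 96 h and 120 h replicate 2, 144 h and 168 h replicates 1 and 2). A further 4 libraries were intermediate: drought 168 h replicate 1 at 0.308, combined 72 h replicate 1 at 0.336, drought 96 h replicate 2 at 0.592 and combined 0 h replicate 1 at 0.683. The remaining 38 lay between 0.777 and 1.29. The 12 libraries are called the second profile below, and the main counts are also given for the 38 alone, a choice made after the data were seen. On the first principal component the 12 lay at 100.4 to 160.3, the 4 intermediate ones at -25.3 to 56.7 and the 38 at -79.0 to -7.15. The largest axis of variation thus separates the second profile, which no control library has. In the 38, combined plants have a lone library at 0, 72, 144 and 168 h and drought plants at 120 h, each assumed to vary like the other groups, so single-time counts there are not replicated in that arm.

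**Figure D2:**
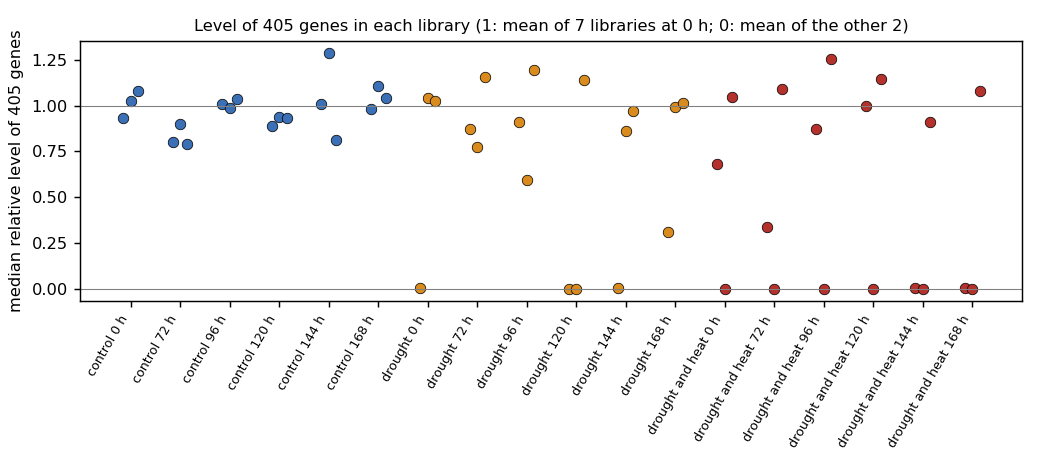
Each point is a library, and the vertical axis is the median relative level of the 405 genes, where 1 is the mean of 7 libraries at 0 h and 0 the mean of the other 2. Of the 54 libraries, 12 lie at 0, all of them drought or combined, 4 lie between and 38 lie at 0.777 or above.

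Drought was compared with control over 72 to 168 h (15 libraries each) to ask which leaf transcripts respond to drying. Averaged over the 5 times, 4473 genes were higher and 3578 lower under drought, 25.2% of the 32011 tested. Most changes were modest, with a median log2 fold change of 0.62 among the higher and -0.60 among the lower genes, and 1120 and 610 changed at least 2-fold. Pavir.3KG282800.v4.1 on chromosome 3K fell from 122.5 ± 96.7 CPM in control to 16.2 ± 3.64 CPM in drought (SD, n = 15 each), with log2 fold change -2.60 ± 0.26 (SE) and edgeR adjusted p = 1.4e-07. In control plants it stood at 229 CPM at 72 h and 27.4 CPM at 168 h, while the drought group means lay between 11.8 and 18.3 CPM (10.2 to 23.5 CPM in single libraries). At 0 h the means were 45.6 CPM in control and 48.1 CPM in drought plants. Pavir.9NG650300.v4.1 on 9N fell from 173.5 ± 96.8 to 37.8 ± 10.5 CPM (SD, n = 15 each; log2 -2.05 ± 0.23, edgeR adjusted p = 5.9e-07). Its control means went from 105.7 CPM at 0 h to 284 CPM at 72 h and 69.8 CPM at 168 h, and its drought means from 92.9 to 38.7 and 41.7 CPM. Pavir.1NG059200.v4.1 on 1N rose from 7.24 ± 11.9 to 49.0 ± 32.5 CPM (SD, n = 15 each; log2 3.26 ± 0.40, edgeR adjusted p = 2.8e-06), and its highest control value, 48.5 CPM, was in a 144 h library. Pavir.5NG177700.v4.1 on 5N was higher by less, at 29.6 ± 7.46 CPM in control and 49.98 ± 9.47 CPM in drought (SD, n = 15 each; log2 0.76 ± 0.09, edgeR adjusted p = 1.7e-06), and stood at 35.9 ± 5.196 CPM in combined plants over 96 to 168 h (SD, n = 12). At 0 h its means were 45.95 CPM in control and 36.6 CPM in drought plants, so part of this gap is a lower level in later controls (23.2 to 34.8 CPM).

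In the 38 libraries, 3611 genes were higher and 3647 lower under drought. Of the genes called in all 54, 3032 were again called higher and 2704 again lower, though the 38 are part of the 54 and no independent sample. The 4 named genes passed again (largest adjusted p 5.5e-04). With libraries of the same number in a treatment allowed to correlate, as they would if they came from the same plants, limma called 175 genes higher and 132 lower, against 3157 and 3500 without that correlation, both chosen after the data were seen. The 4 named genes passed there too (largest adjusted p 0.0195). The 405 genes of the second profile had a median log2 fold change of -0.62 between drought and control, with 11 called lower.

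Followed over time, the genes higher under drought in the mean had a median log2 difference of 0.42 at 72 h, 0.62 at 96 h, 1.02 at 120 h, 0.28 at 144 h and 0.58 at 168 h. The lower genes went through -0.46, -0.50, -1.03, -0.41 and -0.51. The controls at 144 h include replicate 2, whose drought score (described below) was 1.22, against -2.83 and -3.48 in replicates 1 and 3. These medians were not recomputed without it, so the smaller values at 144 h do not show a weaker drought response. Of the higher genes 67.5%, and of the lower genes 81.97%, had the same sign at all 5 times. The genes were called on the mean over these same libraries, so these shares and the medians are partly built in. Tested at single times, edgeR called 15 genes at 72 h (1 higher, 14 lower) and 4075 at 120 h (2218 higher, 1857 lower). It called 0 genes at 96, 144 and 168 h, where 3254, 1960 and 3057 genes had an unadjusted p below 0.05, against 1601 by chance, and DESeq2 called 598, 130 and 413, limma 0 each. The change of the drought response from 72 to 168 h, tested itself, gave 0 genes in edgeR (1094 at unadjusted p below 0.05), 0 in limma and 67 in DESeq2. Single libraries moved these counts. At 72 h, edgeR called 0 genes without control replicate 1 or any of the drought replicates. At 96 h, 52 and 225 genes were called without control or drought replicate 2. At 144 h, there was 1 without control replicate 3, and 21 and 6 without drought replicate 2 or 3, and at 168 h 70 and 633 without drought replicate 1 or 2. At 120 h, 57, 2063 and 1565 genes were called without control replicate 1, 2 or 3, and 1736, 1847 and 2429 without drought replicate 1, 2 or 3. With a model of only the 2 groups compared, whose spread rests on 6 libraries, drought gave 46 genes at 72 h and 2640 at 120 h. Of the 3 drought libraries at 120 h, 2 have the second profile. With the lone drought library left in the 38, edgeR called 0 genes at that time (6501 at unadjusted p below 0.05), but with the level of the 405 genes as a covariate in all 54 it called 4801. At 96 h the 38 libraries gave 349 higher and 103 lower genes.

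**Figure D3:**
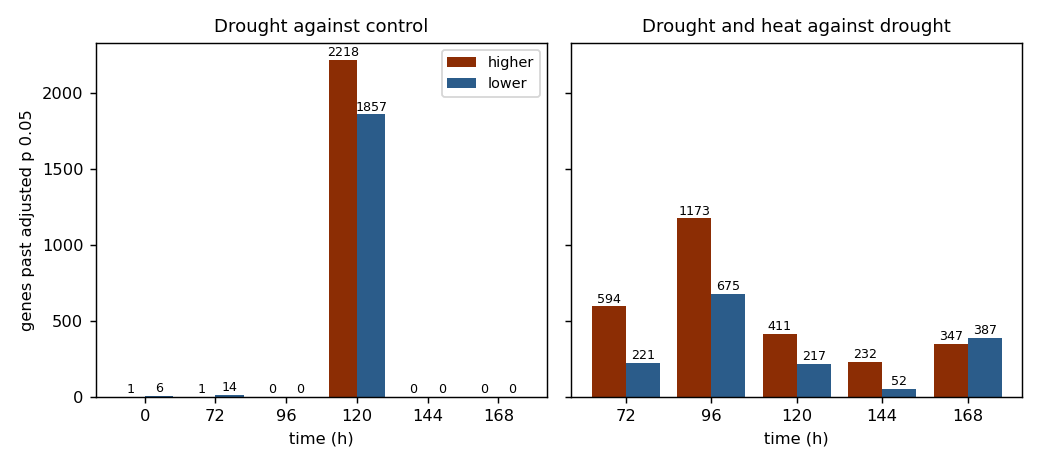
Bars give the number of genes past an edgeR adjusted p of 0.05 at each time in hours, higher or lower, for drought against control (left) and combined stress against drought (right). The drought count is concentrated at 120 h (2218 higher, 1857 lower, and 57 genes in all without control 120 h replicate 1). Combined plants differed from drought plants at 72 h, where the titles give 0 h of heat (594 higher, 221 lower, and 1 gene in all without combined 72 h replicate 3).

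Combined plants were compared with drought plants over 96 to 168 h (12 libraries each) to ask what heat adds, though heat and the separate chamber go together here. In the mean, 5052 genes were higher and 4529 lower in combined plants, 29.9% of those tested, with median log2 fold changes of 0.65 and -0.60. Pavir.5NG283500.v4.1 on 5N rose from 24.6 ± 14.7 CPM in drought to 118.4 ± 72.7 CPM in combined plants (SD, n = 12 each; log2 2.32 ± 0.24, edgeR adjusted p = 7.6e-08), and control plants at these times had 28.5 ± 14.8 CPM (SD, n = 12). At 0 h it already stood at 24.1 ± 2.32 CPM in combined plants, 12.6 ± 3.08 CPM in drought plants and 7.90 ± 0.70 CPM in control plants (SD, n = 3 each). Pavir.1KG415700.v4.1 on 1K rose from 12.1 ± 1.36 to 19.4 ± 2.35 CPM (SD, n = 12 each; log2 0.68 ± 0.07, edgeR adjusted p = 7.6e-08), with controls between them at 15.4 ± 1.49 CPM. At 72 h, with 0 h of heat, combined and drought plants already stood at 16.8 and 11.4 CPM for this gene and at 106.3 and 15.5 CPM for Pavir.5NG283500.v4.1 (means, n = 3 each), so neither difference can be assigned to heat alone. Pavir.5KG244900.v4.1 on 5K fell from 12.5 ± 2.06 to 6.68 ± 1.76 CPM (SD, n = 12 each; log2 -0.94 ± 0.10, edgeR adjusted p = 1.1e-07), and its group means in combined plants were 10.4 CPM at 72 h (12.2 CPM in drought), 8.18 CPM at 96 and 120 h, 5.47 CPM at 144 h and 4.90 CPM at 168 h. Pavir.4NG008300.v4.1 on 4N fell from 28.2 ± 2.05 to 18.1 ± 2.29 CPM (SD, n = 12 each; log2 -0.64 ± 0.07, edgeR adjusted p = 1.1e-07), and control plants had 28.1 ± 2.64 CPM. At 72 h it stood at 25.2 CPM in combined and 29.3 CPM in drought plants. Of the called genes, 91.4% of the higher and 85.7% of the lower ones had the same sign at all 4 times, which is partly built in, since the same libraries gave the calls. In the 38 libraries, 2390 genes were higher and 2308 lower, of which 2189 and 2021 were also called in all 54, and the 4 named genes passed again (largest adjusted p 5.1e-04). With libraries of the same number in a treatment allowed to correlate, limma called 3012 genes higher and 1796 lower, against 5272 and 3981 without that correlation. The 405 genes had a median log2 difference of -0.47, with 3 called lower.

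These differences were not limited to the heated times. At 72 h, when the titles give 0 h of heat, 594 genes were higher and 221 lower in combined than in drought plants. Of the 9581 genes called over 96 to 168 h, 83.6% had the same sign at 72 h, where the median log2 difference was 0.49 for the later higher genes and -0.35 for the later lower ones. The count at 72 h was 1391, 534 and 1 without combined replicate 1, 2 or 3, and 418, 118 and 149 without drought replicate 1, 2 or 3. In edgeR with only the 2 groups compared it was 0 (3447 at unadjusted p below 0.05), while DESeq2 and limma on all 54 called 1819 and 426. At single heated times, 1173 genes were higher and 675 lower at 96 h, 411 and 217 at 120 h, 232 and 52 at 144 h, and 347 and 387 at 168 h. Single libraries moved these counts as well. At 96 h, 868 and 0 genes were called without drought replicate 2 or 3, and 532 and 16 without combined replicate 1 or 2. At 120 h, there were 0, 35 and 53 without drought replicate 1, 2 or 3, and 1 without combined replicate 1 or 2. At 144 h, 40 and 51 were called without drought replicate 2 or 3, and 95 and 65 without combined replicate 2 or 3. At 168 h, there were 119 and 175 without drought replicate 2 or 3, and 2, 144 and 185 without combined replicate 1, 2 or 3. With only the 2 groups compared, edgeR called 51 genes at 96 h and 0 at 120, 144 and 168 h, with 4572, 3489 and 5790 at unadjusted p below 0.05, where DESeq2 on all 54 called 1611, 770 and 2125. The 38 libraries gave 98, 1, 18 and 0 genes at these times in edgeR (3369 at unadjusted p below 0.05 at 168 h, where DESeq2 called 2125 in all 54), and at 72 h, with a lone combined library, 1193 higher and 687 lower. The change of this difference from 96 to 168 h, tested itself, gave 0 genes in edgeR (1586 at unadjusted p below 0.05, against 1601 by chance), 0 in limma and 7 in DESeq2.

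**Figure D4:**
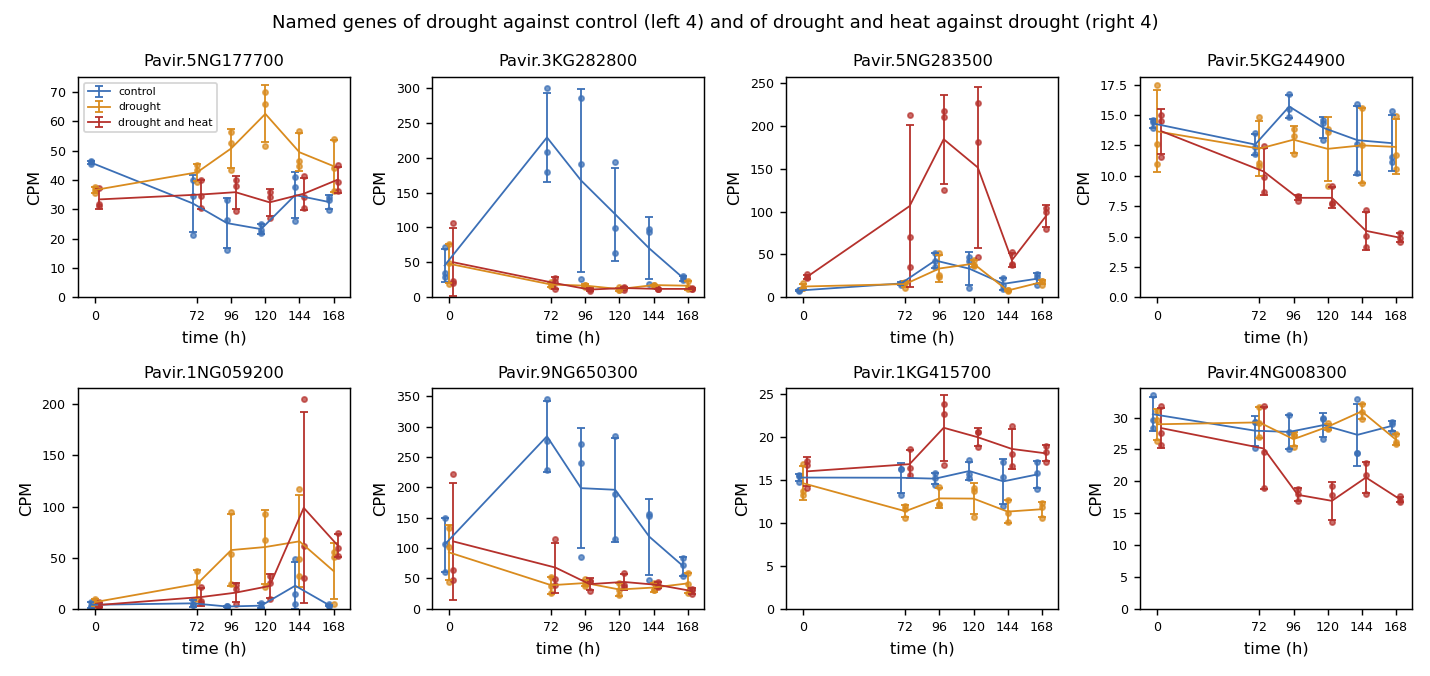
Level in scaled CPM against time in hours for the 4 genes named for drought (left) and the 4 named for combined stress against drought (right). Small points are libraries and lines join group means with SD bars (n = 3), in control, drought and combined plants. Pavir.3KG282800.v4.1 has 229 CPM in control and 18.3 CPM in drought at 72 h, and Pavir.5NG283500.v4.1 has 35.3, 70.7 and 213 CPM in the 3 combined libraries at 72 h.

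With the difference at 72 h subtracted, the comparison planned to take out the chamber, 10 genes were higher and 3 lower. In all 54 libraries, 2645 genes had an unadjusted p below 0.05, against 1601 by chance. The subtracted part rests on 3 libraries per treatment at 72 h, and no self-test was run for this comparison. The small count thus does not show that little difference arose after 72 h. Pavir.9KG619700.v4.1 on 9K had 10.4, 21.4, 29.1, 63.9 and 62.4 CPM in combined plants at 72, 96, 120, 144 and 168 h (means, n = 3 each), and 28.1, 12.7, 12.9, 39.5 and 16.7 CPM in drought plants, with a corrected log2 fold change of 2.56 ± 0.47. Pavir.5NG055600.v4.1 on 5N gave 6.41 ± 1.26, and here drought plants stood at 47.2 ± 26.9 CPM at 72 h (SD, n = 3) against 1.36 ± 0.965 CPM in combined plants. Pavir.9KG127900.v4.1 on 9K (log2 -1.11 ± 0.20) and Pavir.7NG286000.v4.1 on 7N (log2 -1.36 ± 0.26) were lower by this measure. Part of that comes from 72 h, where Pavir.7NG286000.v4.1 stood at 13.7 CPM in drought plants (23.4 to 28.4 CPM later) and 27.4 CPM in combined plants (18.3 to 22.3 CPM later), and Pavir.9KG127900.v4.1 at 24.1 and 35.9 CPM (27.9 to 35.1 and 17.2 to 26.2 CPM later). All 4 had an edgeR adjusted p of 0.0380, and none passed in the 38 libraries (adjusted p 0.596 for each). Their log2 fold changes there, in the order named, were 1.95 ± 0.68, 5.66 ± 1.97, -1.09 ± 0.29 and -1.57 ± 0.38, with the same sign and larger SE. In the 38, edgeR called 0 genes, with 2374 at unadjusted p below 0.05. DESeq2 called 173 genes in all 54 and limma 6. Leaving out drought 72 h replicate 1, 2 or 3 gave 0, 0 and 29 genes, and leaving out combined 72 h replicate 1, 2 or 3 gave 0, 1 and 113. The count was 5 without drought 96 h replicate 1, 3 without drought 120 h replicate 1, 20 without drought 168 h replicate 3, 24 and 1 without combined 96 h replicate 2 or 3, and 0 without combined 168 h replicate 1 or 3.

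Combined plants were compared with control plants over 96 to 168 h (12 libraries each) for the joint effect. In the mean, 7807 genes were higher and 6420 lower, 44.4% of those tested, and 2176 and 1718 changed at least 2-fold. Pavir.9KG414400.v4.1 on 9K rose from 5.62 ± 1.09 to 14.3 ± 2.16 CPM (SD, n = 12 each; log2 1.35 ± 0.12, edgeR adjusted p = 1.0e-09), with drought plants at 6.70 ± 0.98 CPM. Pavir.2KG326800.v4.1 on 2K rose from 3.65 ± 1.38 to 10.05 ± 1.06 CPM (SD, n = 12 each; log2 1.51 ± 0.15, edgeR adjusted p = 2.4e-08), with drought plants at 4.88 ± 1.25 CPM. Pavir.5KG244900.v4.1, named above, fell by this measure too (log2 -1.08 ± 0.10, edgeR adjusted p = 6.2e-09), and Pavir.2NG262500.v4.1 on 2N fell from 33.0 ± 5.56 to 17.5 ± 2.74 CPM (SD, n = 12 each; log2 -0.92 ± 0.09, edgeR adjusted p = 2.4e-08). In the 38 libraries, 4619 genes were higher and 4786 lower, of which 4185 and 4073 were also called in the same direction in all 54. A further 9 genes were called in both but in opposite directions. With libraries of the same number allowed to correlate, limma called 4919 higher and 4763 lower, against 7294 and 6977 without. The 405 genes had a median log2 difference of -1.21, with 63 called lower.

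Drought and combined stress, each against control over 96 to 168 h, shared 2325 higher and 1776 lower genes, and 178 genes were called in opposite directions. Independent lists of these sizes would share 957 and 630. Across genes, which are not independent replicates, the fold changes correlated at 0.716 with covariance 0.425. Since both comparisons use the same controls, unchanged groups simulated against them gave a correlation of 0.4997 and a covariance of 0.0587 (mean of 10 simulations). With the 12 controls split so that each comparison had 6 of its own, the covariance was 0.463 or 0.432, and 828 higher and 651 lower, or 497 and 177, genes were shared. Independent lists of those smaller sizes would share 322 and 139, or 215 and 63.9. All these values take libraries as independent. With libraries of the same number in a treatment allowed to correlate, limma shared 113 higher and 87 lower genes (33.3 and 18.9 for independent lists), against 1410 and 1878 without that correlation. No control library has the second or intermediate profile, while drought and combined libraries at these times do. A difference tied to that profile can therefore enter both comparisons. Neither the simulation nor the split of controls takes it out, and the sharing was not counted in the 38 libraries.

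Neither subgenome held called genes more often by the test. Over the 3 main comparisons and both directions, the shares of K and N genes called differed by odds ratios between 0.95 and 1.05 (Fisher's exact test, smallest adjusted p = 0.432 over subgenomes). For single chromosomes that test, which takes genes as independent, gave its smallest p for J, where 9.94% of 1448 genes were lower in combined than in drought plants (odds ratio 0.659, exact adjusted p = 1.3e-04). Neighbouring genes are called together more often than shuffles allow. When the calls were rotated along the order of identifiers, which keeps neighbours together, no chromosome passed in 114 tests. The adjusted p was 0.652 for J in that comparison, and the smallest was 0.456, for 8K genes higher in combined than in control plants. No chromosome is thus shown to differ, and the calls themselves rest on edgeR with independent libraries.

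Before treatment, at 0 h, drought and control plants of the shared chamber differed in 7 genes (1 higher, 6 lower in drought). That count was 1 and 15 without control replicate 1 or 3, and 0 and 42 without drought replicate 2 or 3, and 0 in edgeR with only the 2 groups compared (954 at unadjusted p below 0.05), against 38 in DESeq2 on all 54. Combined and control plants differed in 4145 genes (1754 higher, 2391 lower in combined). The count was 261 with only the 2 groups compared, 127 without control 0 h replicate 1, 1922 and 1380 without combined 0 h replicate 2 or 3, and the 38 libraries, with a lone combined library at 0 h, gave 239 higher and 357 lower. Control plants changed with time in 3871 genes (F test over the 6 times), 3129 in the 38 libraries and 782 without control 0 h replicate 1.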

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

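Of the alternatives below, leaving out the 12 second-profile libraries, leaving out the 16 of second or intermediate profile, using the level of the 405 genes as a covariate, and both limma settings were chosen after the data were seen. The 3 mean counts (8051, 9581, 14227) stayed within 1.5 times their value with limma (6657, 9253, 14271), DESeq2, its size factors, both filters, the replicate block, models of only the compared groups and each library left out (6085 to 9834, 8452 to 10004, 13107 to 14736). A 2-fold threshold gave 1730, 2060 and 3894. The 11 genes named for them passed in the same direction in 467 of 472 alternative values. The other 5 fell short of the 2-fold threshold: Pavir.5NG177700.v4.1 for drought, Pavir.1KG415700.v4.1, Pavir.5KG244900.v4.1 and Pavir.4NG008300.v4.1 for combined against drought, and Pavir.2NG262500.v4.1 for combined against control. The 11 genes were picked for the smallest p in the same libraries, so these values do not speak for the remaining called genes. Of 176 values for the 4 genes of the comparison with the 72 h difference subtracted, 40 missed the threshold and 0 reversed.

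Without the 12 libraries, combined against drought gave 4319 genes in the mean and 213, 4, 0, 0 and 0 at 72, 96, 120, 144 and 168 h, and combined against control 8742 in the mean and 1293 at 0 h. Drought gave 0, 0, 74 and 0 at 0, 72, 96 and 120 h, and the comparison with the 72 h difference subtracted 0. Without the 16, the combined against drought counts were 4698 and 1880, 98, 1, 18 and 0, those against control 9405 and 596, drought gave 0, 0, 452, 0 and 3 at 0, 72, 96, 120 and 168 h, and the subtracted comparison 0. Both leave fewer libraries per group. With the covariate, drought gave 28 genes at 72 h and 92 at 96 h, and combined against drought 1863 at 168 h.

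Deviations from group means correlated at 0.0955 on average between libraries of the same number in different groups, and at -0.0475 between those of other numbers. Deviations cancel within a group, so the second value follows from the first and is no separate evidence. The lowest pair of the same number and time in different treatments had -0.507. The numbers thus do not pair libraries of different treatments throughout. Whether a number marks the same plants over time within a treatment was not measured apart by these values. Of 54 libraries, 37 correlated best with their own number out of the 3 numbers. Replicate 2 had the lowest drought score in all 10 drought and combined groups from 72 h on. Combined replicate 2 has the second profile at all 6 times. These values are a hint of shared plants or material. With libraries of a number in a treatment correlated, limma gave 307 genes for drought and 4808 for combined against drought in the mean, 30 for the subtracted comparison, 6 and 2527 for drought at 72 and 120 h, and 313, 99 and 116 for combined against drought at 72, 120 and 144 h. Without the correlation it gave 6 for the subtracted comparison, 9 and 2682 for drought at 72 and 120 h, 426, 324 and 148 for combined against drought at 72, 120 and 144 h, and 2327 for control over time. The fall of the drought mean thus came with the correlation, not with limma. With the number as a block 15 of 19 counts stayed within 1.5 times. The others were 26 for the subtracted comparison, 1 for drought at 96 h, and 1040 and 1323 for combined against drought at 120 and 168 h.

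DESeq2 gave 173 for the subtracted comparison, 38, 161, 598, 130 and 413 for drought at 0, 72, 96, 144 and 168 h, 1819, 2994, 1611, 770 and 2125 for combined against drought at 72 to 168 h, 67 and 7 for the changes with time, and 5909 for control over time. Models of only the compared groups gave 0, 46 and 2640 for drought at 0, 72 and 120 h, 0, 51, 0, 0 and 0 for combined against drought at 72 to 168 h, 261 for combined against control at 0 h, 17 for the change of the drought response and 2338 for control over time. The subtracted comparison gave 6 over 96 to 144 h and 190 against the mean of 0 and 72 h. With the controls split, drought and combined stress shared 1479 or 674 genes, and 200 in limma with the correlation. The cause of these moves was not tested.

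Leaving out 1 library ranged from 0 to 113 for the subtracted comparison and from 782 (control 0 h replicate 1) to 4199 for control over time. Drought ranged from 0 to 42 at 0 h, 0 to 15 at 72 h, 0 to 225 at 96 h, 57 to 2429 at 120 h, 0 to 21 at 144 h and 0 to 633 at 168 h. Combined against drought ranged from 1 to 1391 at 72 h, 0 to 1898 at 96 h, 0 to 909 at 120 h, 40 to 341 at 144 h and 2 to 756 at 168 h. Combined against control at 0 h ranged from 127 to 4897, and both changes with time gave 0 genes in edgeR with any library left out. The single libraries behind these moves are named with the results. Behind the 46 counts of 0 among the other alternatives stood 373 to 6501 genes at unadjusted p below 0.05, and behind the 47 with edgeR and a library left out 692 to 5465. The alternatives planned for the gene lists were not run, since no list could be matched. For drought at 96 h, the self-test recovered 6% of 2-fold changes, so changes of that size were mostly not detectable in that comparison.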

Other observations

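All tests in this part were chosen after the results were seen, apart from the values with single libraries left out of the edgeR model without a covariate. Large changes were fewer than the totals show. Drought raised 351 genes and lowered 117 at least 4-fold, and combined stress against control 483 and 287, while combined plants differed from drought plants at least 4-fold in 129 higher and 142 lower genes. At least 16-fold, the counts were 61 and 23 for drought, 100 and 35 for combined stress against control, and 2 and 11 for combined stress against drought. Among 12423 pairs of next-in-number genes, 609 were both called in the same direction under drought, against a mean of 398 and a maximum of 459 in 1000 shuffles. The pairs numbered 709 (maximum 638 in the shuffles) for combined against drought and 1567 (maximum 1347) for combined against control. At 4-fold or more, 25 such pairs stood against a mean of 1.63 and a maximum of 7 in the shuffles for drought, and 30 against a mean of 3.85 and a maximum of 12 for combined against control, while the 2 pairs of combined against drought lay within the shuffles (mean 0.426, maximum 4). Tandem copies that share reads may contribute to the 609 pairs, which no sequence was at hand to examine.

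A drought score was computed for each library from the 200 rising and 200 falling genes with the smallest p at the other times in the 38 first-profile libraries, as the mean log2 CPM of the rising genes minus that of the falling ones. Its median was -2.83 in 15 control, 0.685 in 15 drought and -0.295 in 15 combined libraries. Control 144 h replicate 2 scored 1.22, above the drought median, and the next highest control scored -1.17. The score genes were picked anew for each time, so scores compare best within a time. At 144 h drought replicates 1, 2 and 3 scored 1.15, -0.149 and 0.859, all below that control. Drought 168 h and 96 h replicate 2 scored -1.79 and -1.72, the lowest of the drought libraries. At 168 h control replicates 1, 2 and 3 scored -1.49, -2.13 and -1.17, so drought replicate 2 lay among them. At 96 h the controls scored -4.41, -3.02 and -4.17, all below drought replicate 2. Replicate 2 was the lowest of its 3 in all 10 drought and combined groups from 72 h on, and in 1 of 5 control groups, which points to a structure among the libraries of that number. Without control 144 h replicate 2, 9834 genes were called for drought in the mean, against 8051 with it.

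The near absence of 405 genes from 12 libraries was weighed first. Treatment as its whole cause is argued against by 17 of 30 treated libraries with the genes at full level, since 7 of 10 treated groups hold both kinds, and depth by like totals (median 34.74 M counts in the 12 libraries and 34.71 M in the 38, ratio 1.00). Plants of another genotype were assumed to lose reads of some genes and hardly gain any, if reads were counted on an AP13 reference. The build is not given and this premise was not tested, since genes expressed only in another genotype would count as gains. In all 7 later groups that hold both profiles, 65 of 31598 genes were nearly absent from the second profile and 59 from the first. Losses thus made up 52.4%, short of the 90% set for this explanation. The 31598 leave out the 405 genes and the higher genes of the 0 h search, here taken without its limit on the mean count. The rule first written would have excluded it at that share. Leaving out the 405 and the higher genes also leaves out the largest losses, and with them put back the share was 84.1% (354 and 67 genes). The rule was therefore changed after the first share was seen, and another genotype cannot be told apart from other causes. A mislabelled or exchanged plant stays open, and the labels name AP13 for all samples. For the 4 intermediate libraries, mixing on the linear scale described the genes better than the same step on the log scale in 4 of 4. The linear errors were 0.214 to 0.325 log2 and the log-scale errors 0.221 to 0.353. The margin asked for was the 0.319 log2 error of a first-profile library. It was about as large as the errors themselves and could hardly be met, so missing it decides nothing. The gaps were small, and mixed libraries cannot be told apart from another origin of their levels.

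The difference between combined and drought plants at 72 h, where the titles give 0 h of heat, was weighed next. Its covariance across genes with the later difference was 1.03 times that between the difference at 96 and 144 h and the one at 120 and 168 h (0.797 to 1.329 with each drought or combined library left out), and 1 of the 20 orders of the 6 libraries gave as large a covariance, the real one (0.279, highest other 0.232). With the level of the 405 genes as a covariate, 807 genes were called at 72 h, against 815 without it, which argues against the second or intermediate profile as its whole cause. Here too only counts were compared, not which genes were called. With each of 5 of the 6 libraries left out, the covariate gave 0.729 to 1.80 times the count without it. Without combined 72 h replicate 3, both gave 1 gene, so the count itself rests on that library. A plant difference already there at 0 h, as the whole cause, is argued against by a ratio of 0.323 at that time (0.102 to 0.493 with each drought or combined 0 h library left out). As a part of the cause it stays open. Of the 9581 genes called over 96 to 168 h, 63.6% had the same sign at 0 h, against 83.6% at 72 h. The separate chamber and heat that began before the 72 h sampling may each have produced the 1.03, and they cannot be told apart because the labels give no hour of sampling or of the start of heat.

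The difference between combined and control plants at 0 h was weighed last. With the level of the 405 genes as a covariate, 5007 genes were called, against 4145 without it, which argues against the second or intermediate profile as its whole cause. Only counts were compared, and whether the same genes stayed called was not examined. With each 0 h library of the comparison left out, the covariate gave 0.925 to 2.44 times the count without it, and 310 genes without control 0 h replicate 1. Across genes, drought minus combined at 0 h correlated at 0.732 with control at 0 h minus control at later times (0.475 to 0.823 with each 0 h or control library left out, 0.685 without control 0 h replicate 1), against -0.347 to 0.198 at the other times. Taken alone, drought replicates 1, 2 and 3 gave 0.513, 0.0921 and 0.798, so a state at 0 h that all control and drought libraries share is not shown, and it cannot be told apart from a state of some of them. No biological explanation was tested.

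Other splits of the same libraries were counted for each comparison, the real split included. With 30 splits drawn, 1 of 30 gave as many genes, the real one, for drought in the mean (8051, highest other 12), combined against drought in the mean (9581, highest other 1497), and combined against control in the mean (14227, highest other 138). That argues against chance for these if the libraries are independent. With 30 splits the share cannot fall below 1 of 30, so chance is not excluded. With libraries of a number in a treatment kept together there are 10 splits, too few for a share under 0.05, and the highest other counts were 6548, 5726 and 998, which points to a structure among the libraries of a number. For control over time, 1 of 30 gave as many (3871, highest other 2401). Without control 0 h replicate 1 the real count fell to 782, still above the 574 of the highest other order of the 17 libraries left (1 of 30 as large). The limit of 30 orders and the condition of independent libraries hold there too. For the comparison with the 72 h difference subtracted, 4 of 30 splits gave at least the real 13 genes, and the highest other gave 2689, so chance cannot be excluded, and that many genes points to a structure among the libraries. At single times, 6 libraries make 10 splits, too few for a share under 0.05. For drought, the real and highest other counts were 7 and 258 at 0 h (2 of 10 splits as large), 15 and 0 at 72 h, 0 and 0 at 96 h, 4075 and 0 at 120 h, 0 and 0 at 144 h, and 0 and 32 at 168 h. For combined against drought they were 815 and 79 at 72 h, 1848 and 0 at 96 h, 628 and 8 at 120 h, 284 and 301 at 144 h, and 734 and 5 at 168 h. For combined against control at 0 h they were 4145 and 0.

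Within the second profile, 3 drought and 3 combined libraries at 120 and 144 h gave 0 genes in edgeR, with 3215 at unadjusted p below 0.05. Of 4637 genes called for combined against drought in the 38 libraries and tested here, 95.3% had the same sign.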
